A study of Homo sapiens with 2 samples.

How the data were processed

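RNA of wild-type human neural stem cells was sequenced from 2 cultures that the labels call independent, with 1 library per culture. Both libraries form 1 group, and the replicate number of the labels separates them into the first and the second culture. Neural stem cells are dividing precursors of neurons and glia, and the labels name neither their line nor their donor. Per the labels' protocols, messenger RNA was captured from column-purified RNA and sequenced as single reads of 50 bases on an Illumina HiSeq2500.

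The deposited values are raw counts of reads per gene, made by the authors before deposit and not normalised. Per the submitters' processing notes, the tools used were Trimmomatic 0.39, HISAT2 2.2.1 and HTSeq 0.12.4, on the human build GRCh38 (hg38). The annotation release and the strand setting of the counting are not given in the sources used here, so a gene and an antisense partner could not be told apart. Each file holds 60671 gene identifiers and 5 closing lines that name no gene. These closing lines tally reads that HTSeq left unassigned, and they stayed out of library totals and tests. Of all reads tallied (22492129 in the first culture and 25005215 in the second), 73.7% and 72.3% were assigned to a gene. Reads with several alignments made up 11.7% and 12.1%, reads overlapping more than 1 gene 6.63% and 7.07%, unaligned reads 4.21% and 4.82%, and reads in no gene 3.78% and 3.74%. Such a counting rule can lower the level of a gene whose exons lie under another gene or whose sequence occurs elsewhere in the genome.

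Counts were divided by each library's total of gene-assigned reads and given as CPM (counts scaled to a library total of 1e+06). CPM is not scaled by gene length, so ranks of abundance are ranks of reads, which long transcripts raise. A gene was called detected at 1 CPM or more in both libraries. Gene type, position, exon length (bases in any annotated exon) and exon overlap came from GENCODE release 29 on GRCh38, which holds 58453 of the identifiers; current symbols were found for 60401. The share of a gene's exon bases lying under exons of another gene on either strand, and the share of its 50-base words found in transcripts of another gene, were computed over all annotated transcripts and, added after the levels had been seen, over the principal transcript (best APPRIS rank).

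The choices of this paragraph were made before the data were examined. A set of 24 gene lists with 680 entries (661 distinct genes) covered cell type markers, patterning factors, signalling pathways, disease genes and cell states; 3 listed genes lay outside the background of 19850 protein-coding genes. The number of detected members of each list was compared with the other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Beside it stands the percentile of the list's median log2(CPM + 0.5) among 10000 random lists of the same size. Each gene's reads in the second library, out of its reads in both, were compared with that library's share of all reads by a two-sided exact binomial test, over genes with at least 10 reads in both libraries together, with Benjamini-Hochberg adjustment. For every list with at least 5 such members, the median log2 ratio of CPM (second over first culture, 0.5 CPM added to each) was placed among 10000 random lists matched on mean expression in 20 bins, and a list outside the central 95% was said to stand apart. The common biological coefficient of variation came from edgeR with both libraries as 1 group and TMM scaling, which leaves 1 residual degree of freedom per gene. The named genes are the 15 most abundant protein-coding genes, the anchors of each list with its 3 other most abundant members, further patterning factors at 1 CPM or more, and, among genes past the binomial threshold with a mean of at least 10 CPM, the 10 with the largest log2 ratio in each direction. Members named beyond this rule were chosen after their values were seen: the undetected members of the neural stem and chromatin lists, FABP7 and SOX1, and genes with shared exons. Some genes that meet the naming rule are not described in the text. Genes of the Y chromosome and of X inactivation were left out of every named result.

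Alternatives were TMM and DESeq2 scaling, detection at 0.5 CPM, 5 CPM, 10 reads or 1 RPKM (CPM per kilobase of exon), each library alone, all genes with a read as background, other low-count filters, and fold limits of 1.5 and 2. Added after seeing the data were trends of the ratio with exon length and GC content (lowess, fraction 0.3), random lists matched on expression together with length or GC content (10 bins each, or 5 and 40 bins), and lists without members that share at least 50% of their exons or words. R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.

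The binomial test was tested on simulated data: 200 genes were changed by known folds and the other genes had unchanged means. Of those tested, 56.0% were called at 1.5-fold higher, 49.0% at 1.5-fold lower, 76.0% at 2-fold higher and 76.1% at 2-fold lower, and 5 of 17004 unchanged genes were called. Both simulated libraries varied by sampling of reads only, without variation between cultures. The low share of false calls is therefore set by the test's null and does not cover such variation. The estimate of the coefficient of variation gave 0.0501, 0.0987 and 0.1996 for simulated values of 0.05, 0.1 and 0.2.

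The gene-assigned totals of 16570316 and 18068985 reads make 1 read worth 0.0603 and 0.0553 CPM, and a count of 0 allows up to 3 reads, or 0.181 and 0.166 CPM. Errors are SDs over the 2 cultures. Intervals (95%, Clopper-Pearson on the split of reads), floors and p-values of the binomial test cover counting error only, since reads carry no molecular identifiers. The intervals hold for the ratio without the added 0.5 CPM, so the printed log2 ratio lies closer to no difference than their middle, most at low counts. A test on the reads of 2 libraries compares those libraries and not conditions, and genes are not independent replicates. With 1 group, no comparison between conditions was made.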

Results

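The transcriptome of wild-type human neural stem cells was measured in 2 independent cultures, as part of a study on non-coding regulatory elements and disease-relevant variants. Gene-assigned depth was 16570316 reads in the first culture and 18068985 in the second. At 1 CPM or more in both cultures, 13322 genes were detected, of which 11738 were among 19858 annotated protein-coding genes. Protein-coding genes held 98.2% and 98.0% of the reads, and genes of the mitochondrial genome 3.15% and 2.57%. Across 17126 genes with at least 10 reads in total, the cultures had a Spearman correlation of 0.985; genes are not independent replicates. Levels are given as mean CPM ± SD (n = 2 cultures).

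The 15 most abundant protein-coding genes were led by cytoplasmic actin, with ACTG1 (ENSG00000184009) at 8509 ± 651 CPM and ACTB at 6816 ± 1442 CPM. The tubulins TUBA1A and TUBB, subunits of microtubules, stood at 2933 ± 193 and 2545 ± 24.5 CPM. Nestin (NES, ENSG00000132688), an intermediate filament of neural stem cells encoded on chromosome 1 from 156668763 to 156677397 (GRCh38, minus strand), ranked 9 among protein-coding genes at 2690.0 ± 142 CPM. Mitochondrially encoded MT-CO1, MT-CO2, MT-ND4, MT-CO3 and MT-ND5, subunits of the respiratory chain, lay between 2627 ± 951 CPM (MT-ND5) and 4205 ± 552 CPM (MT-CO1). The remaining members of the top 15 were the elongation factor EEF1A1 (3214 ± 10.6 CPM), the glycolytic enzyme ENO1 (2426 ± 85.8 CPM), the RNA-binding protein HNRNPA2B1 (2359 ± 114 CPM), the imprinted retrotransposon-derived gene PEG10 (2322 ± 516 CPM) and the chaperone HSP90AA1 (2284 ± 101 CPM). The 100 most abundant genes held 16.8% ± 0.232 of the gene-assigned reads.

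Markers of neural stem cells and radial glia were abundant in both cultures. SOX2 (ENSG00000181449; chromosome 3, 181711924 to 181714436), a transcription factor that maintains neural progenitors, reached 407 ± 78.0 CPM, and its relative SOX1 163 ± 53.1 CPM. Vimentin (VIM) stood at 2117 ± 557 CPM, with 46.0% of its principal transcript under exons of another gene. The receptor phosphatase PTPRZ1 reached 1139 ± 344 CPM and N-cadherin (CDH2) 574 ± 35.4 CPM. The chromatin protein HMGA2 stood at 555 ± 80.9 CPM and the fatty acid binding protein FABP7 at 304 ± 42.9 CPM. PAX6, a regulator of dorsal progenitors, was counted at 20.1 ± 0.862 CPM, but 75.1% of its principal transcript lies under exons of another gene, so its level is uncertain. In all, 25 of 30 listed markers were detected, against 59.1% of other protein-coding genes (Fisher's exact test, adjusted p = 0.0139), with a list median at percentile 100 of random lists. The undetected members were the Notch target HES5 (1.31 ± 0.737 CPM, below 1 CPM in the first culture), FAM107A (0.375 ± 0.0179 CPM), TNC (0.116 ± 0.0071 CPM), and HOPX and EMX2 with 0 reads.

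**Figure D1:**
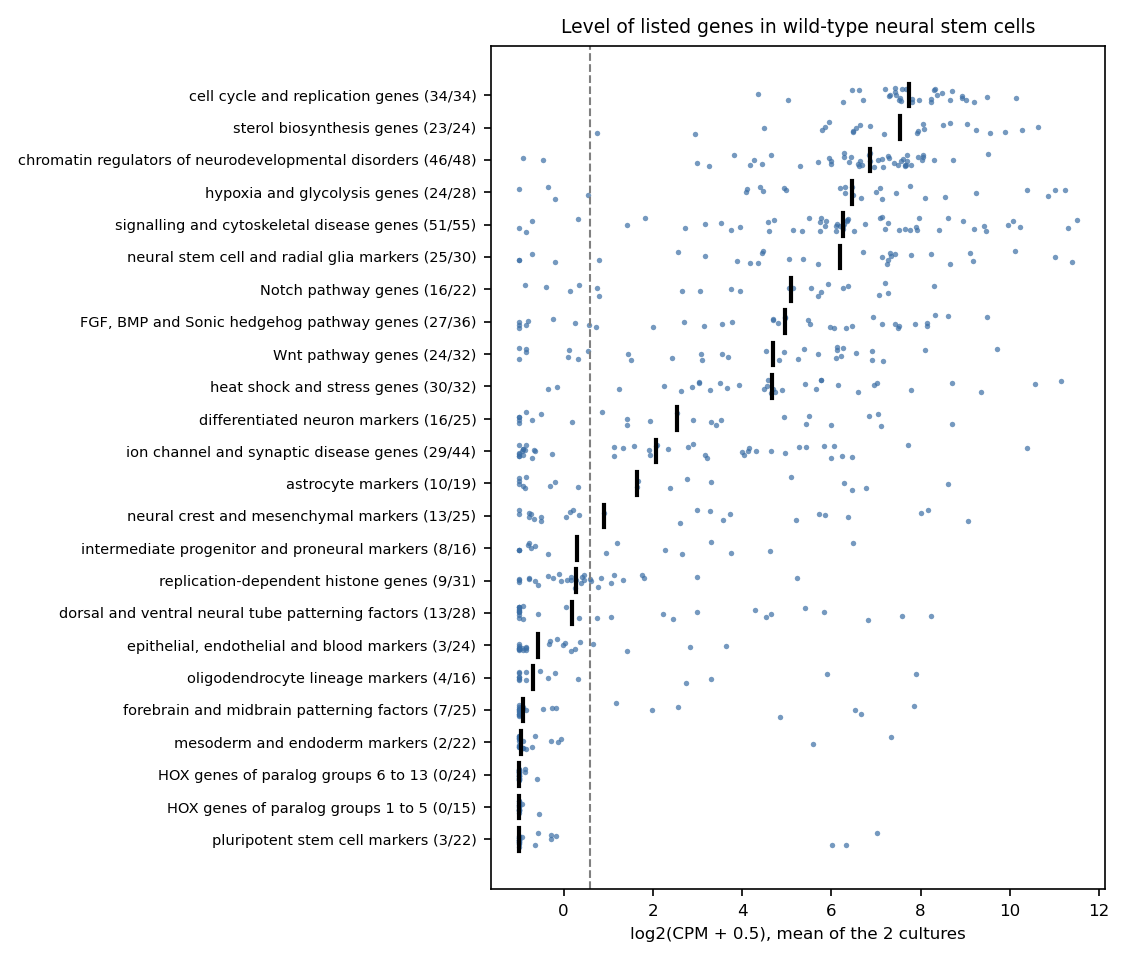
Mean log2(CPM + 0.5) over the 2 cultures (horizontal axis) of every protein-coding member of the 24 gene lists, with 1 point per gene, the list median as a black bar, the detection level of 1 CPM as a dashed line and detected over listed members in brackets. Cell cycle genes (34 of 34 detected) lie at the top and both groups of HOX genes (0 of 15 and 0 of 24) among the lowest lists.

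Cell cycle and replication genes were expressed throughout: 34 of 34 members were detected (Fisher's exact test, adjusted p = 2.43e-07), with a median of 214 CPM. The replicative helicase subunits MCM7 and MCM3 reached 1133 ± 87.4 and 516 ± 3.72 CPM, the sliding clamp PCNA 489 ± 34.4 CPM and topoisomerase TOP2A 724 ± 137 CPM. The proliferation antigen MKI67 stood at 631 ± 324 CPM and differed by more than sampling of reads between the cultures, with a log2 ratio of -1.10 (second over first).

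Most pluripotency markers were not detected. NANOG had 0 reads, which allows up to 0.181 and 0.166 CPM, and POU5F1 stood at 0.148 ± 0.132 CPM, with 63.4% of the 50-base words of its principal transcript also present in other genes. Of 22 listed markers, 3 were detected (Fisher's exact test, adjusted p = 6.39e-05): the DNA methyltransferase DNMT3B at 131 ± 21.3 CPM, the RNA-binding protein LIN28A at 80.4 ± 2.96 CPM and the chromatin-associated protein DPPA4 at 64.8 ± 12 CPM.

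Markers of differentiated neural cells were mixed. Microtubule-associated MAP2 (432 ± 155 CPM), the neurofilament NEFM (142 ± 50.5 CPM) and the RNA-binding protein ELAVL3 (132 ± 2.55 CPM) led the neuronal list. For NEFM, 42.4% of the principal transcript lies under exons of another gene. The immature-neuron protein DCX stood at 2.2 ± 0.0527 CPM, and RBFOX3, the NeuN antigen of mature neurons, had 2 reads in the first culture and 0 in the second. Neuronal tubulin TUBB3 was counted at 11 ± 0.839 CPM, with 89.5% of its principal transcript under exons of another gene. Of the neuronal markers, 16 of 25 were detected (Fisher's exact test, adjusted p = 0.688). Among intermediate progenitor and proneural markers, 8 of 16 were detected (Fisher's exact test, adjusted p = 0.524), led by HES6 (90.9 ± 29.3 CPM), BTG2 (24.4 ± 3.16 CPM) and the Notch ligand DLL1 (13.2 ± 2.22 CPM), while the cortical progenitor factor EOMES had 0 reads.

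Astrocyte markers were detected in 10 of 19 cases (Fisher's exact test, adjusted p = 0.671). Glutamine synthetase (GLUL, 393 ± 24.0 CPM), clusterin (CLU, 110 ± 0.788 CPM) and the growth factor receptor FGFR3 (88.5 ± 8.55 CPM) were the highest, whereas the glial filament GFAP stood at 0.322 ± 0.142 CPM and the water channel AQP4 at 2.88 ± 1.65 CPM. Oligodendrocyte lineage markers were detected less often than other protein-coding genes, in 4 of 16 cases (Fisher's exact test, adjusted p = 0.0139). The myelin enzyme CNP (238 ± 38.8 CPM), the regulator MYRF (60.0 ± 6.41 CPM) and the proteoglycan CSPG4 (9.59 ± 2.91 CPM) led this list, and the lineage factor OLIG2 (0.772 ± 0.239 CPM) and the precursor receptor PDGFRA (1 read in each culture) stayed under 1 CPM. The oligodendrocyte call ended with detection at 5 CPM and with all genes having a read as background (Fisher's exact test, adjusted p = 0.0624 and 0.787).

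Among markers of other lineages, 13 of 25 neural crest and mesenchymal genes were detected, a share that did not pass the threshold against other genes (Fisher's exact test, adjusted p = 0.592). The fibrillar collagen COL3A1 reached 535 ± 54.8 CPM, the surface protein THY1 289 ± 16.8 CPM and fibronectin (FN1) 274 ± 131 CPM, while COL1A1 stood at 36.5 ± 5.95 CPM and the mesenchymal factor TWIST1 at 12.8 ± 1.18 CPM. Mesoderm and endoderm markers were detected in 2 of 22 cases (Fisher's exact test, adjusted p = 5.88e-06), namely the VEGF receptor KDR (167 ± 57.5 CPM) and the chemokine receptor CXCR4 (47.4 ± 1.67 CPM). MESP1 followed at 0.558 ± 0.619 CPM, and the germ layer factors TBXT and SOX17 had 0 reads. Epithelial, endothelial and blood markers were detected in 3 of 24 cases (12.5%; Fisher's exact test, adjusted p = 1.08e-05; 25% in the first culture alone, adjusted p = 0.0015), the endothelial genes CDH5 (12.1 ± 2.01 CPM), TEK (6.86 ± 2.58 CPM) and PECAM1 (2.17 ± 0.01 CPM). Epithelial EPCAM stood at 0.314 ± 0.103 CPM and the leukocyte antigen PTPRC at 1 read in each culture.

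Among patterning factors of the neural tube, EN2 (ENSG00000164778; chromosome 7, 155458129 to 155464831), a homeobox gene of the midbrain-hindbrain boundary, reached 237 ± 68.6 CPM, and GBX2 (ENSG00000168505; chromosome 2, 236165236 to 236168369), a homeobox gene of the anterior hindbrain, 300.2 ± 26.1 CPM. PAX5 and PAX8, paired-box factors expressed at that boundary, stood at 28.5 ± 5.42 and 3.48 ± 0.481 CPM. The forebrain-midbrain factor OTX2 had 1 read in the first culture and 0 in the second. The nuclear receptors NR2F1 (104 ± 32.7 CPM) and NR2F2 (92.6 ± 4.13 CPM), LHX2 (5.46 ± 0.973 CPM) and OTX1 (1.77 ± 0.149 CPM) completed the 7 of 25 forebrain and midbrain factors detected, fewer than among other protein-coding genes (Fisher's exact test, adjusted p = 0.0039).

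Of the dorsal and ventral patterning factors, 13 of 28 were detected (Fisher's exact test, adjusted p = 0.243). The Iroquois genes IRX2 (195 ± 43.4 CPM), IRX1 (25.5 ± 8.57 CPM), IRX3 (23.3 ± 7.31 CPM) and IRX5 (19.5 ± 5.50 CPM) were all present, as were the dorsal zinc finger genes ZIC2 (114 ± 25.6 CPM), ZIC1 (57.1 ± 8.87 CPM) and ZIC5 (42.2 ± 6.89 CPM), with ZIC4 at 4.31 ± 1.33 CPM. The ventral factors NKX6-2 and NKX6-1 stood at 7.71 ± 2.88 and 1.61 ± 0.310 CPM, and DLX1 at 1.19 ± 0.114 CPM. The ventral forebrain factor NKX2-1 and the dorsal factor PAX7 had 0 reads.

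No HOX gene was detected, neither of paralog groups 1 to 5 (0 of 15; Fisher's exact test, adjusted p = 5.88e-06) nor of groups 6 to 13 (0 of 24; Fisher's exact test, adjusted p = 1.11e-08). HOXB2, of the hindbrain, was the highest at 0.196 ± 0.192 CPM, followed by HOXD13 at 0.169 ± 0.153 CPM. HOXB9 and HOXA7 had 0 reads in the first culture and 2 in the second, HOXB3 0 and 1, and HOXA2, HOXA3, HOXA4, HOXA9 and HOXA10 had 0 in both. For HOXA7, 62.5% of the exon bases lie under another gene on either strand, which may limit its count, depending on the strand setting of the counting. With only genes that had a read as background, which leaves out most HOX genes, the calls ended for HOX groups 1 to 5 (Fisher's exact test, adjusted p = 0.581), HOX groups 6 to 13 (adjusted p = 0.353), forebrain and midbrain factors (adjusted p = 1), pluripotency markers (adjusted p = 0.581) and mesoderm and endoderm markers (adjusted p = 0.106).

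**Figure D2:**
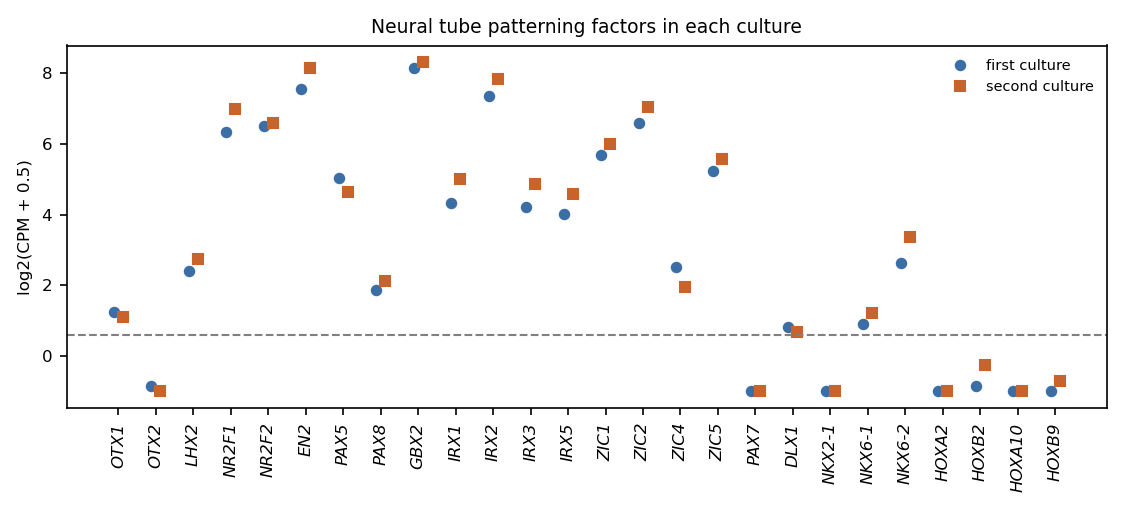
Level of neural tube patterning factors as log2(CPM + 0.5) (vertical axis) in the first culture (circles) and the second (squares), with the detection level of 1 CPM as a dashed line. EN2 (237 CPM on average) and GBX2 (300.2 CPM) lie highest, whereas NKX2-1, PAX7, HOXA2 and HOXA10 had 0 reads in both cultures.

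Signalling pathway genes were expressed at list medians of 34.4 CPM (Notch), 25.6 CPM (Wnt) and 30.8 CPM (FGF, BMP and Sonic hedgehog). The list medians of log2(CPM + 0.5) lay at percentiles 97.4, 96.1 and 99.0 of random lists. The receptors NOTCH3 (315 ± 28.0 CPM), NOTCH1 (155 ± 24.2 CPM) and NOTCH2 (85.6 ± 33.5 CPM) and the coactivator MAML1 (147 ± 20.3 CPM) were present, and 16 of 22 Notch genes were detected (Fisher's exact test, adjusted p = 0.351). Of the Wnt genes, 24 of 32 were detected (Fisher's exact test, adjusted p = 0.104), with beta-catenin (CTNNB1) at 842 ± 39.1 CPM, the receptors FZD2 and FZD3 at 275 ± 11.9 and 144 ± 12 CPM, and the target genes AXIN2 and LEF1 at 30.3 ± 3.98 and 7.94 ± 0.821 CPM. FGF, BMP and Sonic hedgehog genes were detected in 27 of 36 cases (Fisher's exact test, adjusted p = 0.0922). The receptor FGFR1 (719 ± 30.3 CPM), the FGF feedback genes DUSP6 (395 ± 23.9 CPM) and SPRY4 (325 ± 60.8 CPM), the FGF-responsive factor ETV4 (283 ± 18.8 CPM) and the hedgehog receptor PTCH1 (186 ± 35.7 CPM) led that list. These 3 lists passed the threshold at a detection level of 0.5 CPM (Fisher's exact test, adjusted p = 0.0359 for Notch, 0.0154 for Wnt and 0.0154 for FGF, BMP and Sonic hedgehog).

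Genes linked to neurodevelopmental disorders were detected to different extents. Chromatin regulators were present in 46 of 48 cases (Fisher's exact test, adjusted p = 9.57e-08), among them the remodelling subunits SMARCA4 (727 ± 40.9 CPM), SMARCB1 (317 ± 34.1 CPM, with 56.1% of its principal transcript under another gene) and ARID1B (87.4 ± 18.7 CPM), the cohesin subunit SMC1A (442 ± 168 CPM) and the helicase CHD8 (199 ± 56.8 CPM). The undetected members were BCL11A (0.231 ± 0.0142 CPM) and the histone methyltransferase NSD1 (1 read in the first culture, 0 in the second). Signalling, cytoskeletal and RNA-binding genes were detected in 51 of 55 cases (Fisher's exact test, adjusted p = 2.53e-07), led by TUBA1A, TUBB and the RNA-binding proteins HNRNPU (1200.3 ± 77.5 CPM) and HNRNPK (1076 ± 99.5 CPM). Ion channel and synaptic genes were detected in 29 of 44 cases (Fisher's exact test, adjusted p = 0.524). The glucose transporter SLC2A1 reached 1346 ± 50.0 CPM and dynamin DNM1 74.8 ± 6.53 CPM, while the sodium channel SCN2A stood at 3.76 ± 1.09 CPM. Scaled by exon length, 31.8% of the channel and synaptic genes passed 1 RPKM, which turned the direction of this list (Fisher's exact test, adjusted p = 0.0221), whereas with all genes having a read as background 74.4% were detected, more than among other genes (adjusted p = 0.0046).

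Metabolic and stress genes were widely expressed. Sterol biosynthesis genes were detected in 23 of 24 cases (Fisher's exact test, adjusted p = 0.0002), with the synthase HMGCS1 at 1596 ± 220.0 CPM and squalene synthase FDFT1 at 1240.5 ± 61.4 CPM. Hypoxia and glycolysis genes were detected in 24 of 28 cases (Fisher's exact test, adjusted p = 0.0064), led by ENO1, GAPDH (2080.0 ± 88.0 CPM) and PKM (1852 ± 34.4 CPM), with PGK1 at 373 ± 2.75 CPM and the hypoxia target VEGFA at 20.5 ± 1.13 CPM. Heat shock, unfolded protein and immediate early genes were detected in 30 of 32 cases (Fisher's exact test, adjusted p = 4.9e-05). The chaperones HSPA8 (1511 ± 182 CPM) and HSPA5 (660 ± 17.7 CPM) and the stress factor ATF4 (416 ± 11.3 CPM) were abundant, and the immediate early gene FOS stood at 4.28 ± 0.0983 CPM. Replication-dependent histone genes, whose transcripts lack the poly(A) tail used for capture, were detected in 9 of 31 cases (Fisher's exact test, adjusted p = 0.0018), with a list median at percentile 9.14 of random lists. H2BC9 reached 36.9 ± 3.20 CPM, H1-2 7.60 ± 1.78 CPM and H4C3 0.287 ± 0.0641 CPM, and H2BC12 (3.01 ± 0.266 CPM, with 74.1% of its words shared with other genes) and H2BC21 (2.88 ± 0.150 CPM) completed the leading members. The histone call ended at a lower detection level and in the second culture alone: 61.3% of members passed 0.5 CPM in both cultures and 41.9% passed 1 CPM in the second (Fisher's exact test, adjusted p = 1 and 0.0644), and held in the first culture alone (32.3%; adjusted p = 0.0054).

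The cultures were then compared with each other to see how far genes differed beyond sampling of reads. PAPPA (ENSG00000182752; chromosome 9, 116153804 to 116402322), a secreted metalloprotease, had 149 CPM in the first culture and 44.5 CPM in the second, a log2 ratio of -1.73 (95% interval -1.86 to -1.63). In the other direction, PCLAF (ENSG00000166803; chromosome 15, 64364311 to 64387687), a PCNA-binding factor, had 8.21 and 22.5 CPM, a log2 ratio of 1.40 (1.17 to 1.75). The exact binomial test called 7007 of 17126 genes (40.9%), 4217 higher and 2790 lower in the second culture. Without a low-count filter it called 6564 of 27283 genes (24.1%), and with 1 CPM in both libraries 6917 of 13322 (51.9%). A difference of at least 1.5-fold was met by 1712 of the called genes and one of at least 2-fold by 533. The share of calls that were higher depended on scaling: it was 60.2% with library totals, 42.2% with TMM (2785 of 6598 calls) and 48.3% with DESeq2 size factors (3241 of 6715), because these scalings shift every log2 ratio by -0.11 and -0.07. The common biological coefficient of variation was 0.175, from 1 residual degree of freedom per gene.

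Other genes with large differences spanned several functions. Lower in the second culture were the immune ligand NCR3LG1 (-1.64), the centrosomal CEP295 (-1.42), the dystrophin relative UTRN (-1.41), the zinc finger gene ZKSCAN8 (-1.40), the mitochondrial MT-ATP8 (-1.39), the non-coding LINC01043 (-1.30), the tetraspanin CD37 (-1.26), PRRC2C (-1.26) and MXRA5 (-1.25). Higher were TSNAX (1.33), the unnamed non-coding gene ENSG00000269044 (1.19), TMEM50B (1.17), GATAD1 (1.15), C4orf48 (1.12), the respiratory subunit NDUFC2 (1.12), the non-coding EMSY-DT (1.11), TMEM41B (1.09) and the taurine-pathway enzyme CSAD (1.07). All values are log2 ratios of genes past the exact binomial threshold, and all 20 genes of this set kept their direction and call under TMM and DESeq2 scaling. The size of their ratios left little room for another outcome, since these scalings shift every log2 ratio by only -0.11 and -0.07.

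Differences followed exon length. Across 9616 genes with a mean of at least 10 CPM, the log2 ratio and exon length had a Spearman correlation of -0.459, across genes. Of 10 groups of genes ordered by length, the shortest had a median log2 ratio of 0.28 and 69.0% of its genes were called higher in the second culture, while the longest had a median of -0.26 and 60.1% were called lower. The correlation with GC content was 0.191. Of 10 groups ordered by GC content, the highest had a median log2 ratio of 0.27, with 64.4% of its genes called higher. The lowest group had a median of 0.02.

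**Figure D3:**
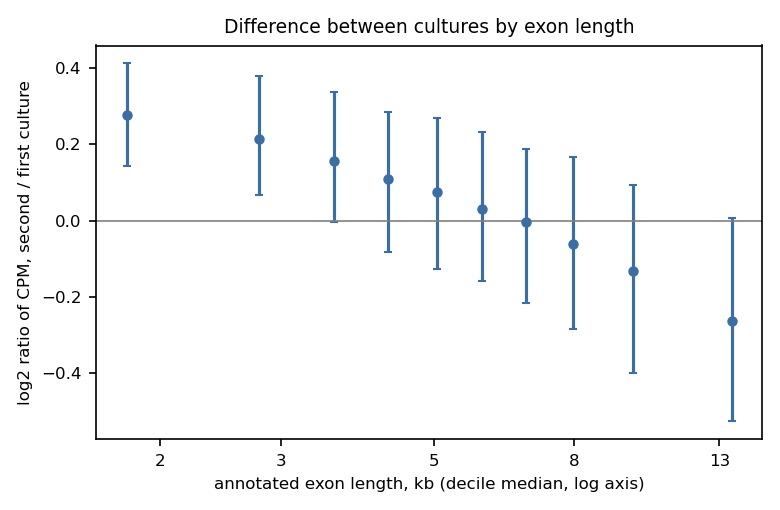
Median log2 ratio of CPM, second over first culture (vertical axis), in 10 groups of genes ordered by annotated exon length (horizontal axis, kb, log scale), with bars from the lower to the upper quartile of the genes. The median goes from 0.28 in the shortest group to -0.26 in the longest.

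Of 22 lists with enough members, 6 stood apart from random lists of the same expression. The percentiles were not adjusted over the 22 lists. Chromatin regulators had the lowest median log2 ratio, -0.38 (percentile 0.0, or 3.31 and inside the central 95% when matched on exon length in 40 bins), with 4 members higher and 33 lower in the second culture, and 4 and 34 adjusted over the list alone. Among these, SMC1A differed by -0.79, CHD8 by -0.59 and ARID1B by -0.44, while SMARCB1 differed by 0.22. Epithelial, endothelial and blood markers had a median of -0.32 (percentile 0.22, with 0 higher and 3 lower, 0 and 2 adjusted over the list alone). This median covers 12 members, although only 3 of the list reached 1 CPM in both cultures, so it rests mostly on low counts. The detected members TEK, CDH5 and PECAM1 differed by -0.73, -0.33 and -0.01. Neural crest and mesenchymal markers had a median of -0.29 (percentile 0.04; 0 higher and 8 lower, likewise adjusted over the list alone), with FN1 at -1.01. Ion channel and synaptic genes had a median of -0.17 (percentile 0.12; 3 higher and 12 lower, 3 and 13 adjusted over the list alone), and the signalling, cytoskeletal and RNA-binding genes -0.08 (percentile 1.84; 12 higher and 23 lower, 13 and 23 adjusted over the list alone). Dorsal and ventral patterning factors had a median of 0.33 (percentile 99.2; 9 higher and 1 lower, likewise adjusted over the list alone), with NKX6-2 at 0.73, IRX1 at 0.69 and ZIC4 at -0.57.

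The other lists lay within the central 95%. Cell cycle genes had a median log2 ratio of 0.13 (percentile 94.1), with 18 higher and 10 lower, and neural stem cell markers -0.07 (percentile 5.67), with 9 higher and 12 lower. TMM scaling, which shifts every log2 ratio, put these medians at 0.03 and -0.18. It put that of the signalling, cytoskeletal and RNA-binding genes at -0.18. Forebrain and midbrain factors had 0.32 (percentile 96.0), with EN2 at 0.60 and NR2F1 at 0.65 higher and PAX5 at -0.38 lower. With random lists matched on exon length as well, the channel and synaptic list (percentile 21), the signalling and cytoskeletal list (percentile 65.9) and the dorsal and ventral list (percentile 97.2) no longer stood apart, and the stress list did (percentile 1.82). The chromatin list lay outside the central 95% with 10 bins of length (percentile 1.48) and inside it with 40 bins (percentile 3.31), so its call did not hold in every length match. Outside it in both length matches were the neural crest and mesenchymal list (percentiles 0.055 and 0.035), the epithelial, endothelial and blood list (0.38 and 0.195) and the stress list (1.82 and 1.69). The neural crest list and the epithelial list also lay outside when matched on GC content (0.05 and 0.16), and the stress list did not (28.7).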

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

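Chosen only after the data were seen were the tests of exon length, GC content, the share of cycling cells and the principal transcript, of which only the GC content tests were written before their own outcome was known. With 1 group of 2 cultures, the design names no biological explanation, and none was tested between groups.

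Reads that overlapped more than 1 gene model are a signal outside the gene counts that was not analysed further: 6.63% of all reads in the first culture and 7.07% in the second. A set of 334 genes for ribosomes, proteasomes, respiration and other core machinery shows where such reads may be missing. Of these, 4 stayed under 1 CPM in the second culture or in both: MRPL53 (1 and 0 reads), MRPS24 (20 and 10), NDUFA7 (6 and 13) and PSMD5 (3 and 6). MRPS24 lay above 1 CPM in the first culture. Pooled over all annotated transcripts, 0.0% of these 4 had at least 50% of their exons under another gene and 0.0% had at least 50% of their 50-base words shared, measures that unused transcripts dilute. Over the principal transcript, 75% of the 4 were covered at that level (MRPS24 85.7%, NDUFA7 78.7%, MRPL53 52.3%), against 24 of 330 other core genes (Fisher's exact test, p = 0.0018), so counting that leaves out overlapping exons is a candidate explanation for these 3. Of the 4, 3 also had at least 50% of the 50-base words of the principal transcript shared. Shared sequence is thus a further candidate, not compared here with the other core genes. For PSMD5, 0.0% of the principal transcript was covered in GENCODE 29, and its cause stays open because the annotation the authors counted on is not given in the sources used here.

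The difference between the cultures covered 7007 of 17126 genes. Simulated sampling of reads from 1 common profile gave 0 calls (0.0% of those observed), but the binomial test takes such sampling as its null, so this outcome was fixed beforehand and decides nothing. Removing the trend with GC content left a number of calls equal to 92.4% of those before, and removing the trend with exon length 86.9%, with 4993 of 6987 calls shared in the latter case. The length trend removed 21.8% of the variance of the log2 ratio and the GC content trend 6.67%. The remaining calls cannot exclude either property as the whole cause. Annotated length and GC content may differ from those of the transcripts expressed, and the binomial test calls small remaining ratios at this depth. A difference between the cultures themselves or in RNA handling and library preparation stays open, and with 1 library per culture these cannot be separated.

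Chromatin regulators were lower in the second culture, with a median log2 ratio of -0.38. Among random lists matched on expression and GC content, the median lay at percentile 0.0, which argues against GC content. The share of cycling cells stays open: the cell cycle list lay at percentile 64.65 of lists matched on expression and length, but its members went both ways (18 higher and 10 lower, with MKI67 at -1.10 and TOP2A at -0.39) with an SD of 0.33, more than the distance between its median (0.02 above the middle of its matched range) and that of the chromatin list (0.15 below). This SD is a spread of genes, over ratios not corrected for length, and not the error of a median. Setting it against the distance therefore decides nothing. Exon length stays open too: the chromatin list lay at percentile 1.48 of lists matched in 10 bins of length, outside the central 95%, but at 3.31 with 40 bins, inside it. Its median exon length was 14584 bases, so a list effect and a length effect cannot be told apart here.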

How the results depend on the processing

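The alternatives with exon length, GC content, finer bins and shared sequence were chosen after seeing the data. No paired analysis was possible because the series has only 1 group. Of 240 list shares recomputed under 10 alternatives, 215 kept their side of the threshold, and 12 of 24 lists did so throughout. Leaving out 31 members that share sequence changed no call. Lists that passed in neither setting counted as kept whatever their direction. Some of these rose with genes that had a read as background: dorsal and ventral 46.4% to 72.2%, astrocyte 52.6% to 62.5%, proneural 50.0% to 61.5%, neural crest 52.0% to 56.5%. They lay below other genes in the main test and above them with that background. With all genes that had a read as background, which drops silent genes by construction, detection no longer passed for pluripotency (33.3%), oligodendrocyte (40%), mesoderm and endoderm (18.2%), HOX 1 to 5 (0.0%), HOX 6 to 13 (0.0%) and histone genes (32.1%), turned to the other side for forebrain and midbrain factors (50.0%, adjusted p = 1), and passed for neuronal (76.2%), Wnt (80.0%), FGF, BMP and hedgehog (81.8%) and synaptic genes (74.4%). At 0.5 CPM the shares were 86.4% (Notch), 84.4% (Wnt) and 83.3% (FGF, BMP and hedgehog), at 10 reads 86.4%, 81.3% and 80.6%, all now past the threshold, while histone genes no longer passed (61.3% and 54.8%). At 5 CPM oligodendrocyte markers lost their call (25%) and the FGF list gained it (72.2%). At 1 RPKM the Wnt (71.9%) and FGF (72.2%) lists gained it, and synaptic genes turned to fewer than other genes (31.8%). Histone genes ranged from 32.3% to 41.9% with a single library, and lost their call in the second culture alone. Epithelial, endothelial and blood markers went from 12.5% to 25% in the first culture alone and kept their call. The cause of these shifts was not tested. Fold limits cut the genes differing between cultures to 1712 (1.5-fold) and 533 (2-fold) by construction. The coefficient of variation moved from 0.175 to 0.176 without a low-count filter and 0.169 at 1 CPM. With random lists matched on expression, 6 lists stood apart, with 10 bins of length as well 4, and with 40 bins 3, of which the stress list was not among the 6. The share of reads in the top genes was 4.16% for 10 genes, 37.2% for 500 and 15.5% without mitochondrial genes. All 40 recomputed ratios of named genes kept their direction and call, which the size of these ratios made near certain. Of 128 list medians between cultures, 117 kept their call. Depth limits genes near 0 reads, for which up to 0.181 and 0.166 CPM cannot be excluded.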

Other observations

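The genes of this part were chosen after their values were seen. Of the long non-coding RNAs, SNHG14, from the imprinted region of chromosome 15, led with 240.3 ± 46.5 CPM (n = 2 cultures), followed by MIAT at 223 ± 27.3 CPM, FGD5-AS1 at 212 ± 28.4 CPM and nuclear MALAT1 at 209 ± 48.7 CPM. NORAD, a sponge of Pumilio proteins, stood at 168 ± 51.7 CPM, TUG1 at 158 ± 40.9 CPM and the snoRNA host genes SNHG1 and GAS5 at 163 ± 7.68 and 108 ± 18.5 CPM. PANTR1, which neighbours the neural factor gene POU3F3, reached 128 ± 32.2 CPM, and SOX21-AS1, antisense to a neural SOX gene, 41.8 ± 0.350 CPM. This order is by reads and not scaled by length: annotated exons hold 43324 bases in SNHG14, 3631 in GAS5 and 844 in PANTR1.

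Further genes were picked from the 100 most abundant. The protease inhibitor A2M stood at 2082 ± 545 CPM, the matrix protein SPARC at 1830.0 ± 192 CPM, the growth factor MDK at 1230.1 ± 254 CPM, the basement membrane chains COL4A2 and LAMC1 at 1154 ± 217 and 1023 ± 273 CPM, and lipoprotein lipase LPL at 1412 ± 165 CPM. Among the same 100 genes were SCD at 1615 ± 285 CPM, FADS2 at 1512 ± 14.1 CPM and FASN at 894 ± 191 CPM.

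NSD1, a histone methyltransferase gene linked to an overgrowth disorder, had 1 read in the first culture and 0 in the second, although 46 of 48 listed chromatin regulators were detected. Of its exon bases 3.01% lie under another gene in GENCODE 29, and 0.0% of its principal transcript. The level of NSD1 was the lowest of that list, with BCL11A next at 4 reads in each culture. Since the annotation release and the strand setting of the counting are not given in the sources used here, these reads do not show that NSD1 was not expressed.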
